A study of Drosophila melanogaster with 24 samples.

How the data were processed

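RNA from whole male flies aged 1 to 7 days was sequenced as 24 libraries: 3 genotypes (wild type, heterozygous and homozygous for a deletion of Rel, all described as a yw background) by 2 injury states (uninjured, or 4 h after traumatic brain injury), with 4 libraries per group. Per the labels' protocols, flies were kept at 25 °C and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. The labels do not state whether the kit or the counting used strand, so overlapping and antisense genes are uncertain. They do not say whether the 4 libraries of a group come from separate cultures, vials or days.

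The authors deposited a table of RSEM expected counts per gene, a table of expected counts per transcript, and tables of their own gene comparisons with log2 fold changes and p-values adjusted for multiple testing. Per the submitters' processing notes, the tools were CASAVA, STAR 2.4.2a, RSEM 1.2.22 and edgeR 3.10.5, with genome build dm6. The annotation used and the role of each tool are not stated in the labels. The deposited gene table held 17768 genes, of which 1271 had no count in any library and 17671 had an identifier in the name table used here. It had 0 columns of other samples and 0 values that were not whole numbers, so rounding the expected counts changed nothing. Symbols are those of the deposited files, where the Bomanins BomS1, BomS2, BomS3 and BomBc1 appear as IM1, IM2, IM3 and IM23. Coordinates are those of Ensembl release 115, which uses dm6 coordinates, counted from 1.

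Library totals ranged from 6543632 to 14660491 counts. Gene counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) factors, the filterByExpr filter (13868 genes kept) and 1 mean per group over all 24 libraries, which leaves 18 residual degrees of freedom. The test is two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 9 comparisons were injury within each genotype, each mutant genotype against wild type within each injury state, and 2 differences of injury responses (each mutant genotype minus wild type). Fold changes are given as log2 values with their standard error, taken as the size of the log2 fold change over the square root of its F. A fold against a group with 0 counts is given as a bound, with 3 counts assumed over the 4 libraries of that group. Against a group with 1 to 3 counts it is the ratio of counts per effective library size, with a 95% exact Poisson interval of the lower count. Sequenced copies made by PCR are not independent molecules, so these intervals and bounds cover counting error only. CPM values use the effective library size and are given as mean ± SD over 4 libraries.

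Before the data were examined, 24 lists of genes were written down: antimicrobial peptides, Bomanins and other Toll peptides, the Imd, Toll, JAK-STAT with Turandot, and JNK, wound and death pathways, heat shock, detoxification, sugar and starvation, digestive enzymes, glycolysis and hypoxia, activity-regulated genes, clock, neuron, glia, eye and phototransduction, muscle, hemocyte and melanization, fat body, testis and germline, accessory gland, female and ovary, ribosomal proteins, and stock markers. The comparisons, tests and alternative settings were fixed at the same time. Below, the list of Bomanins and other Toll peptides is called the Bomanins for short, although it is not limited to Bomanin genes. The 23 lists with at least 3 measured members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 207 tests. The same tests were repeated with a correlation estimated from the data and with fry. A score per library, the mean log2(CPM + 0.5) over all 15 members of the antimicrobial peptide list, was compared between groups with a two-sided exact permutation test over 70 assignments, which cannot give a p below 0.0286, adjusted over the 7 pairwise comparisons. The list tests and the summed CPM used 14 of these members, without edin, which was too low to be tested.

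The genes named were set by a rule fixed beforehand. Rel comes first. Then come the 5 largest increases and 5 largest decreases per comparison among called genes with at least 1 CPM in the higher group and no overlap between the libraries of the groups. Then come 2 to 4 members, by smallest adjusted p, of each list with at least 2 called members or a camera call. Members of the antimicrobial peptide and Imd lists may be named in every comparison, and a gene named in 1 comparison may be followed in the others. Genes chosen after their values were seen are said to be so.

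The fit was tested on simulated counts drawn with the real mean of each gene over all 24 libraries, its dispersion and the library sizes, with 200 genes changed in 1 group at a time and at most 13793 genes tested. For injury in wild type it recovered 28.0% of genes changed 1.5-fold, 66.7% of those changed 2-fold, 94.0% at 4-fold and 97.0% at 8-fold. For the difference of injury responses between homozygotes and wild type the shares were 6.67%, 39.5%, 81.6% and 93.6%, and between heterozygotes and wild type 9.76%, 42.8%, 84.9% and 94.9%. In the uninjured libraries it recovered 73.0% of 2-fold changes between homozygotes and wild type.

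The alternative settings fixed beforehand were median-ratio factors, no filter on low counts, a filter of more than 1 CPM in at least 4 libraries, a fit of only the groups compared, the replicate number as a block, limma voom, DESeq2 1.42.0, an adjusted p under 0.01, a change of at least 2-fold, each library left out in turn, a pseudocount of 5 CPM and CPM by total counts for the score, and the other set tests. Chosen after seeing the data were thinning every library to 6543632 counts, the log2 library total as a covariate, and keeping only libraries with more than 9000000 counts. Other splits of the same libraries were refitted with only the groups concerned: all 35 for a pairwise comparison and 100 drawn splits for each difference of responses. Pairs of libraries within a group were compared for identity, and no duplicate was found (36 pairs, r from 0.941 to 0.988 across genes, which are not independent replicates). The deposited transcript table was not tested here. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.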

Results

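The comparisons ask whether Rel genotype changes the transcript response of whole male flies to brain injury. Libraries held 6543632 to 14660491 counts, so 3 counts in a library correspond to 0.205 to 0.458 CPM, and 13868 genes were tested. Total counts overlapped between groups: 6987499 to 13244524 in uninjured and 6543632 to 13233888 in injured wild type, 8544785 to 13190387 and 7374597 to 13717380 in heterozygotes, and 9992750 to 13710472 and 6715949 to 14660491 in homozygotes. The p-values measure the spread between these libraries, because the labels do not say that the 4 libraries of a group were separate cultures. The lists and tests were chosen before the data were examined, except where stated. Values after ± are standard errors for log2 fold changes and SD over 4 libraries for CPM.

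Rel had 456, 962, 1016 and 752 counts in the 4 uninjured wild-type libraries (69.8 ± 9.84 CPM) and 783, 1989, 1219 and 1860 in the injured ones (145 ± 22.6 CPM). Heterozygotes had 694, 273, 336 and 517 counts uninjured (38.8 ± 12.4 CPM) and 906, 571, 850 and 376 injured (61.9 ± 19.0 CPM). Homozygotes had 1, 0, 0 and 0 counts uninjured and 0 counts in each of the 4 injured libraries. The wild-type level was therefore 3316-fold (595 to 131000) that of uninjured homozygotes, and at least 1991-fold that of injured homozygotes. Rel rose after injury in wild type (log2 fold change 1.05 ± 0.22, adjusted p = 0.00603). In heterozygotes the change was 0.67 ± 0.22 and did not pass (adjusted p = 0.0865), and the difference between these responses did not pass either (-0.38 ± 0.31, adjusted p = 1.00). Injured heterozygotes had less Rel than injured wild type (-1.22 ± 0.22, adjusted p = 0.0113), a call that ended without heterozygous injured library 2 (0.0524), 4 (0.0641) or wild-type injured library 3 (0.0523), adjusted p in parentheses. In uninjured heterozygotes the difference was -0.85 ± 0.22 and did not pass (adjusted p = 0.123). Of the stock markers, w was at 7.11 ± 1.55 CPM in uninjured wild type and 7.09 ± 1.77 CPM in uninjured homozygotes and passed in no comparison, and y was too low to be tested.

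**Figure D1:**
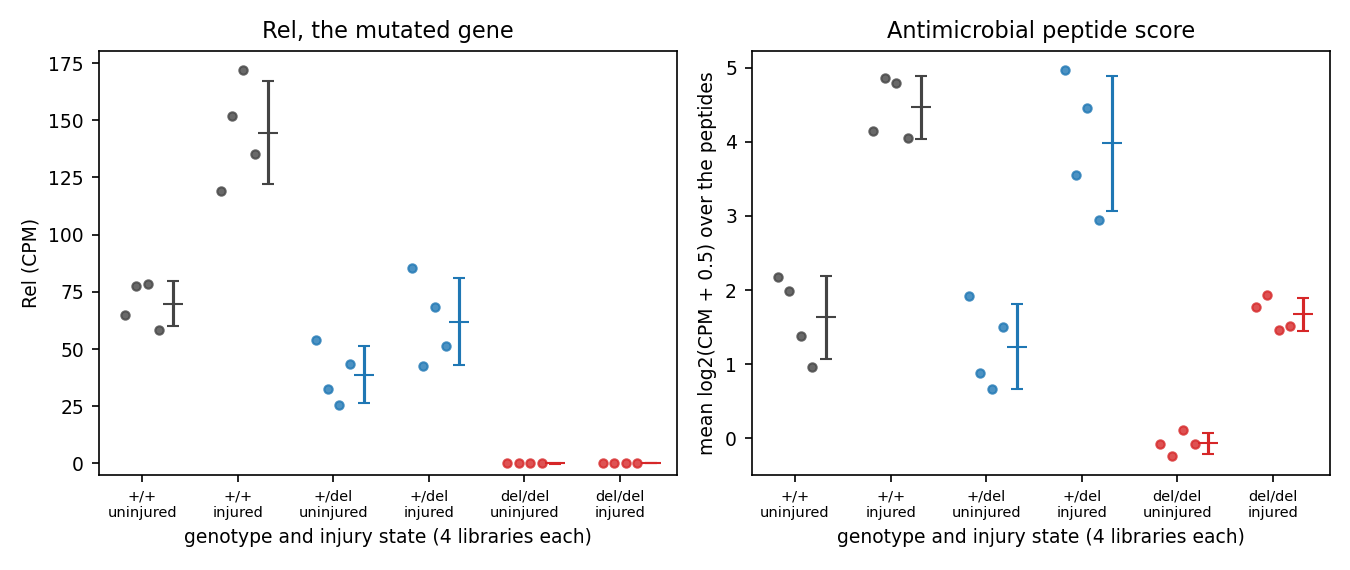
Rel level (CPM) and the antimicrobial peptide score (mean log2 of CPM + 0.5 over the list) in each library, by genotype and injury state; points are libraries (4 per group) and the marks beside them are mean ± SD. Homozygous libraries have 0 or 1 Rel counts, and their score rises from -0.07 to 1.67 after injury against 1.63 to 4.47 in wild type.

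Injury in wild type raised antimicrobial peptide, Bomanin and JAK-STAT genes within 4 h (4 libraries against 4). On the log2 scale Mtk rose by 4.08 ± 0.54 (adjusted p = 4.57e-05), Drs by 2.97 ± 0.42 (adjusted p = 8.63e-05), and PGRP-SB1 by 3.67 ± 0.46 (adjusted p = 2.69e-05). AttC (4.49 ± 0.60), CecC (4.66 ± 0.63), DptB (4.23 ± 0.69), AttA (3.88 ± 0.68), Dro (3.36 ± 0.63) and Def (2.18 ± 0.45) rose too. Reads of attacin, cecropin and Bomanin genes can be shared between near-identical copies, so their single values are uncertain. DptA rose from 8.21 ± 9.15 to 61.2 ± 29.6 CPM (2.99 ± 0.68, adjusted p = 0.0111), a call that ended without wild-type uninjured library 3 (0.0521), 4 (0.0673). Of the antimicrobial peptides, 12 of 14 measured members were higher, 0 lower and 2 did not pass (13 higher and 0 lower adjusted over the list alone), with a median of 3.32 and a camera adjusted p of 9.69e-25. Of the Bomanins and other Toll peptides, 16 of 17 measured members were higher, 0 lower and 1 did not pass (17 higher and 0 lower adjusted over the list alone), with a median of 2.21 and a camera adjusted p of 8.95e-30, with IM1 at 3.21 ± 0.43 and IM2 at 2.67 ± 0.37. Of the Imd pathway, 7 of 22 measured members were higher, 0 lower and 15 did not pass (11 higher and 0 lower adjusted over the list alone), with a median of 0.37 and a camera adjusted p of 5.39e-10, with PGRP-LB at 1.56 ± 0.19, pirk at 1.89 ± 0.31 and PGRP-SD at 2.42 ± 0.42. PGRP-SA rose by 2.52 ± 0.29.

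Some members of the JAK-STAT, JNK, heat shock, Toll pathway, detoxification and activity-regulated lists also rose in injured wild type. Socs36E rose by 1.55 ± 0.20 (adjusted p = 3.83e-05), dome by 0.92 ± 0.13, upd3 by 2.58 ± 0.54 and Tep2 by 1.41 ± 0.25. Of the JAK-STAT and Turandot list, 9 of 18 measured members were higher, 0 lower and 9 did not pass (13 higher and 0 lower adjusted over the list alone), with a median of 1.48 and a camera adjusted p of 6.66e-15. Ets21C rose by 1.87 ± 0.25, puc by 0.85 ± 0.18, Gadd45 by 1.12 ± 0.20 and Mmp1 by 0.82 ± 0.16. Of the JNK, wound and death list, 7 of 21 measured members were higher, 0 lower and 14 did not pass (9 higher and 1 lower adjusted over the list alone), with a median of 0.21 and a camera adjusted p of 0.000191 (adjusted p = 0.364 with an estimated correlation). Hsp70Ab rose by 2.14 ± 0.30, which its near-identical copies make uncertain, and l(2)efl by 1.38 ± 0.22. Of the heat shock list, 6 of 21 measured members were higher, 0 lower and 15 did not pass (8 higher and 0 lower adjusted over the list alone), with a median of 0.35 and a camera adjusted p of 1.06e-07 (adjusted p = 0.157 with an estimated correlation). In the Toll pathway list dl rose by 1.09 ± 0.15 and nec by 1.24 ± 0.25: 7 of 20 measured members were higher, 0 lower and 13 did not pass (8 higher and 0 lower adjusted over the list alone), with a median of 0.33 and a camera adjusted p of 5.78e-06 (adjusted p = 0.451 with an estimated correlation). GstD1 rose by 1.01 ± 0.17 and GstD9 by 0.83 ± 0.14. In detoxification, 6 of 35 measured members were higher, 0 lower and 29 did not pass (9 higher and 1 lower adjusted over the list alone), with a median of 0.27 and a camera adjusted p of 2.97e-05 (adjusted p = 0.278 with an estimated correlation). Arc1 rose by 1.54 ± 0.21 and Arc2 by 1.39 ± 0.23, while of the activity-regulated list as a whole, 3 of 12 measured members were higher, 0 lower and 9 did not pass (3 higher and 0 lower adjusted over the list alone), with a median of 0.07 and a camera adjusted p of 0.0747.

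Among called genes with at least 1 CPM in the higher group and no overlap between libraries, the largest increases in wild type were lncRNA:IBIN, 71.9-fold (24.6 to 349) higher, Fst (5.71 ± 0.82), Acbp6 (5.40 ± 0.91), CecB and CecC. ninaD rose by 3.65 ± 0.46 and sxe2 fell (-1.49 ± 0.21, adjusted p = 7.81e-05), as did CG31205 (-1.47 ± 0.30, adjusted p = 0.00372). In total 525 genes passed, 465 higher and 60 lower, and 246 of them changed at least 2-fold. Over all genes tested, the 4 libraries of one state did not overlap the 4 of the other in 1809 (13.04%), where chance gives 2.86%. Without uninjured wild-type library 4 the count was 302, with 258 higher. The lower genes were 38 and 29 without uninjured library 1 and 3, and 28 and 37 without injured library 1 and 3. Of the 58 named calls, 46 held with each library left out in turn.

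The eye, ribosomal protein, digestive enzyme and neuron lists also had camera calls in injured wild type, none of which held with an estimated correlation. Of the eye and phototransduction list, 1 of 25 measured members was higher, 2 lower and 22 did not pass (1 higher and 8 lower adjusted over the list alone), with a median of -0.41 and a camera adjusted p of 1.28e-05 (adjusted p = 0.609 with an estimated correlation). Of ribosomal proteins, 0 of 40 measured members were higher, 0 lower and 40 did not pass (0 higher and 0 lower adjusted over the list alone), with a median of 0.39 and a camera adjusted p of 8.09e-09 (adjusted p = 0.674 with an estimated correlation). For digestive enzymes the camera adjusted p was 0.00429 and for neuron genes 0.0410 (0.841 and 0.847 with an estimated correlation). The lists without a camera call were fat body (0.501), hemocyte and melanization (0.771), glia (0.913), glycolysis and hypoxia (0.862), clock (0.725), muscle (0.984), sugar and starvation (0.436), testis and germline (0.344), accessory gland (0.0547) and female and ovary (0.0776), with camera adjusted p in parentheses. Of 24 female and ovary genes 7 were measured, and psd rose in wild type (4.37 ± 0.92, adjusted p = 0.00700), a gene singled out after its values were seen. The mean log2 CPM over the 7 genes was 2.67 in injured wild-type library 4, against 1.38 to 1.59 in the other injured wild-type libraries. The rise of psd was not examined without library 4.

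Heterozygotes raised the same kinds of genes after injury (4 libraries against 4). Drs rose by 3.66 ± 0.45 (adjusted p = 1.98e-05), Mtk by 3.44 ± 0.52 (adjusted p = 0.000217), and DptA by 5.11 ± 0.78 (adjusted p = 0.000273), from 1.91 ± 1.55 to 66.8 ± 60.3 CPM. PGRP-SB1 rose by 2.95 ± 0.44, AttC by 4.48 ± 0.61, Dro by 4.11 ± 0.65, IM1 by 2.61 ± 0.42 and IM2 by 2.74 ± 0.37. Of the antimicrobial peptides, 13 of 14 measured members were higher, 0 lower and 1 did not pass (13 higher and 0 lower adjusted over the list alone), with a median of 3.55 and a camera adjusted p of 3.84e-21. Of the Bomanins, 15 of 17 measured members were higher, 0 lower and 2 did not pass (17 higher and 0 lower adjusted over the list alone), with a median of 1.97 and a camera adjusted p of 6.48e-25. Of the Imd pathway, 6 of 22 measured members were higher, 0 lower and 16 did not pass (9 higher and 0 lower adjusted over the list alone), with a median of 0.27 and a camera adjusted p of 4.78e-08, with PGRP-LB at 1.44 ± 0.18 and imd at 0.50 ± 0.11. upd3 rose by 2.92 ± 0.52, TotM by 4.68 ± 0.85 and Socs36E by 1.55 ± 0.20, and of the JAK-STAT list, 8 of 18 measured members were higher, 0 lower and 10 did not pass (12 higher and 0 lower adjusted over the list alone), with a median of 0.92 and a camera adjusted p of 1.05e-09. Def rose by 2.21 ± 0.50 (adjusted p = 0.0103), a call that ended without heterozygous injured library 2 (0.0558) or heterozygous uninjured library 1 (0.0529). lncRNA:IBIN was 211-fold (37.8 to 8324) higher, and CG7017 at least 16.9-fold higher.

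Ets21C (1.98 ± 0.25), Gadd45 (1.13 ± 0.20), Thor (1.10 ± 0.18), Hsp70Ab (2.80 ± 0.31), l(2)efl (1.75 ± 0.22), GstD1 (0.99 ± 0.17), Arc1 (1.82 ± 0.21), Pepck1 (1.76 ± 0.25) and ninaD (3.56 ± 0.44) also rose in heterozygotes. Prm rose by 0.89 ± 0.14 (adjusted p = 0.000423). Of the muscle list, 5 of 20 measured members were higher, 0 lower and 15 did not pass (10 higher and 0 lower adjusted over the list alone), with a median of 0.45 and a camera adjusted p of 6.17e-08 (adjusted p = 0.359 with an estimated correlation). Of the heat shock list, 10 of 21 measured members were higher, 0 lower and 11 did not pass (12 higher and 1 lower adjusted over the list alone), with a median of 0.72 and a camera adjusted p of 4.95e-09 (adjusted p = 0.113 with an estimated correlation). Of ribosomal proteins, 0 of 40 measured members were higher, 0 lower and 40 did not pass (18 higher and 0 lower adjusted over the list alone), with a median of 0.49 and a camera adjusted p of 3.7e-10 (adjusted p = 0.629 with an estimated correlation). For JNK, wound and death genes the camera adjusted p was 0.00118, for detoxification 0.0287, for digestive enzymes 0.00114, for eye genes 0.000127 and for neuron genes 0.00105, none of which passed with an estimated correlation. Activity-regulated genes had a median of -0.02 but a mean of 0.31 and a camera call upward (0.0483, or 0.704 with an estimated correlation). CG4950 fell (-2.15 ± 0.39, adjusted p = 0.00130), and lncRNA:CR46156 (-2.22 ± 0.50), Nepl19 (-1.67 ± 0.35), Mdr65 (-1.08 ± 0.20) and Est-6 (-0.66 ± 0.15) fell too. In total 658 genes passed, 450 higher and 208 lower, 271 of them at least 2-fold. Over all genes tested, the libraries did not overlap in 1154 (8.32%, chance 2.86%). The count was 380 without uninjured heterozygous library 1, 1495 without uninjured library 3 (906 higher) and 382 without injured library 2. The lower genes were 69, 589 and 115 without uninjured library 1, 3 and 4, and 71 and 120 without injured library 2 and 4. Of the 76 named calls, 56 held with each library left out in turn.

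Homozygotes, with 0 or 1 Rel counts per library, also raised a part of the immune genes after injury (4 libraries against 4). Mtk rose from 0.501 ± 0.394 to 32.6 ± 12.3 CPM (5.91 ± 0.68, adjusted p = 6.23e-06), and Drs from 6.25 ± 4.61 to 63.7 ± 22.4 CPM (3.33 ± 0.44, adjusted p = 3.69e-05). Dro was 103-fold (28.4 to 847) higher and AttA rose by 6.59 ± 0.89 (adjusted p = 4.22e-05). IM1 rose by 4.05 ± 0.45 (adjusted p = 4.36e-06), IM2 by 3.47 ± 0.38, IM3 by 3.56 ± 0.41 and IM23 by 6.31 ± 0.81. DptA did not change detectably (0.24 ± 1.35, adjusted p = 0.939), at 0.524 ± 0.224 and 0.628 ± 0.333 CPM, and neither did Def (-1.18 ± 1.18, adjusted p = 0.591). PGRP-SB1 did not pass either (1.60 ± 0.52, adjusted p = 0.0724). Its 4 injured libraries (3.36 to 6.05 CPM) nevertheless lay above the 4 uninjured ones (0.698 to 2.05 CPM), a separation seen in 11.6% of all tested genes. PGRP-SA (2.03 ± 0.30), PGRP-SD (3.45 ± 0.48) and PGRP-LB (1.08 ± 0.19) rose. Of the antimicrobial peptides, 7 of 14 measured members were higher, 0 lower and 7 did not pass (9 higher and 0 lower adjusted over the list alone), with a median of 3.03 and a camera adjusted p of 8.01e-09 (adjusted p = 0.230 with an estimated correlation), and with members at 0 counts in a group set at their bound the median was 2.50. Of the Bomanins, 15 of 17 measured members were higher, 0 lower and 2 did not pass (15 higher and 0 lower adjusted over the list alone), with a median of 2.92 and a camera adjusted p of 1.22e-24. Of the Imd pathway, 7 of 22 measured members were higher, 0 lower and 15 did not pass (11 higher and 0 lower adjusted over the list alone), with a median of 0.33 and a camera adjusted p of 5.14e-06 (adjusted p = 0.113 with an estimated correlation).

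Several of these calls in homozygotes lay near the threshold. With adjusted p in parentheses, AttB (2.74 ± 0.66) lost its call without homozygous injured library 2 (0.0606) or homozygous uninjured library 2 (0.0517). AttC (3.61 ± 1.05) lost it without homozygous injured library 1 (0.121), 2 (0.0895) or homozygous uninjured library 1 (0.0788), 2 (0.125), 3 (0.0772), 4 (0.0943), at log2 fold changes of 3.21 to 3.84. DptB (5.08 ± 1.38) lost it without homozygous injured library 1 (0.0539), 2 (0.0686) or homozygous uninjured library 1 (0.0707), 2 (0.0849), 3 (0.0544), 4 (0.0874), at 4.73 to 5.79. pirk (1.14 ± 0.34) lost it without homozygous injured library 1 (0.122), 2 (0.144), 4 (0.0530) or homozygous uninjured library 1 (0.0952), 2 (0.112), 3 (0.0662), 4 (0.124), at 0.96 or more.

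Some members of the JAK-STAT, JNK, activity-regulated and Toll pathway lists rose in homozygotes too. upd3 rose by 3.37 ± 0.51 (adjusted p = 0.000144), upd2 by 2.67 ± 0.46 and Socs36E by 1.71 ± 0.20, and of the JAK-STAT list, 10 of 18 measured members were higher, 0 lower and 8 did not pass (15 higher and 0 lower adjusted over the list alone), with a camera adjusted p of 6.9e-13. Ets21C rose by 2.24 ± 0.25, Gadd45 by 1.52 ± 0.20, Mmp1 by 1.32 ± 0.16 and Thor by 1.66 ± 0.18, and of the JNK, wound and death list, 12 of 21 measured members were higher, 0 lower and 9 did not pass (12 higher and 0 lower adjusted over the list alone), with a median of 0.54 and a camera adjusted p of 2.44e-09 (adjusted p = 0.0640 with an estimated correlation). Arc2 rose by 1.66 ± 0.23 (adjusted p = 5.57e-05) and sr by 1.08 ± 0.21, and of the activity-regulated list, 4 of 12 measured members were higher, 0 lower and 8 did not pass (8 higher and 0 lower adjusted over the list alone), with a median of 0.44 and a camera adjusted p of 1.29e-07 (adjusted p = 0.0617 with an estimated correlation). dl rose by 1.53 ± 0.15 and nec by 1.62 ± 0.25, and of the Toll pathway, 7 of 20 measured members were higher, 0 lower and 13 did not pass (11 higher and 0 lower adjusted over the list alone), with a median of 0.39 and a camera adjusted p of 1.22e-07 (adjusted p = 0.359 with an estimated correlation). Hsp70Ab (2.73 ± 0.31), stv (1.18 ± 0.19), drpr (0.73 ± 0.15), moody (1.00 ± 0.19), ImpL2 (1.00 ± 0.22), Tig (1.56 ± 0.21) and Pepck1 (1.71 ± 0.25) rose, while CG18302 (-2.39 ± 0.28), lncRNA:CR43452 (-2.74 ± 0.45), CG33557 (-1.86 ± 0.37), Hml (-1.59 ± 0.34) and Mdr65 (-1.01 ± 0.20) fell. Camera adjusted p was 8.35e-06 for heat shock, 0.00188 for neuron, 0.000345 for ribosomal, 0.00686 for testis, 0.0145 for accessory gland, 0.0306 for clock and 0.0175 for sugar and starvation genes, none of which passed with an estimated correlation. In total 813 genes passed, 653 higher and 160 lower, 259 of them at least 2-fold. Over all genes tested, the libraries did not overlap in 1607 (11.6%, chance 2.86%). The count was 538, 515 and 484 without uninjured homozygous library 1, 2 and 4, and 1582 without injured library 4 (1097 higher). The higher genes were 423 without uninjured library 4. The lower genes were 95, 55 and 61 without uninjured library 1, 2 and 4, and 78, 106 and 485 without injured library 2, 3 and 4. Of the 68 named calls, 48 held with each library left out in turn.

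**Figure D2:**
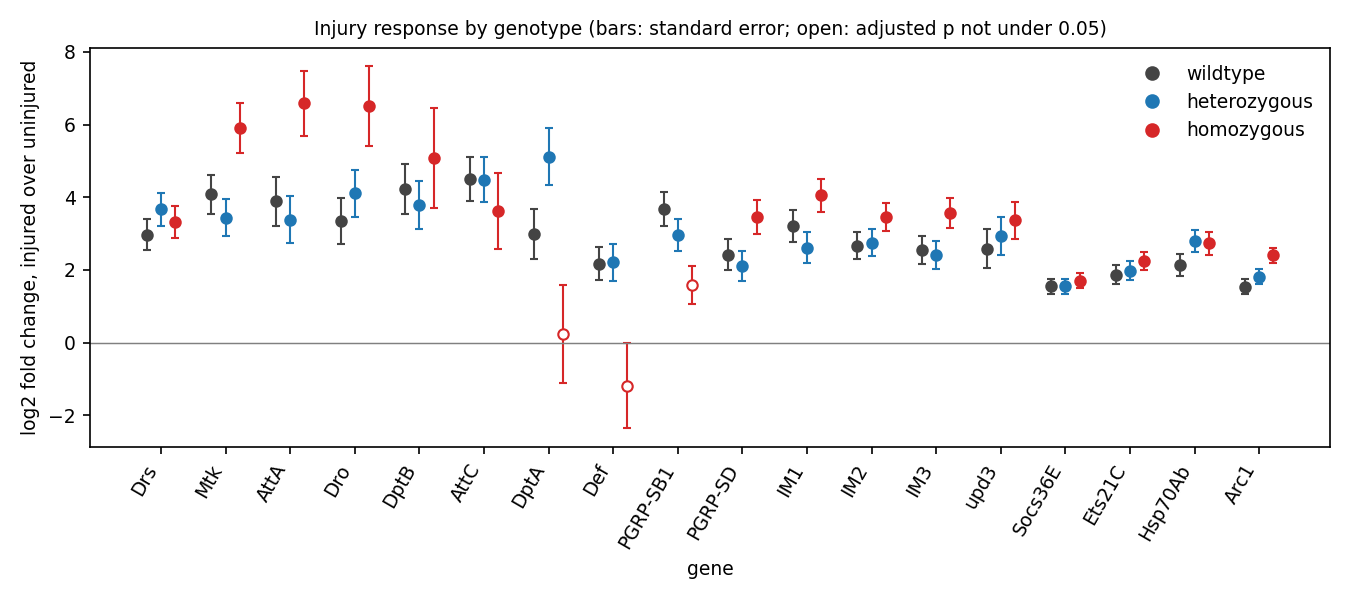
Injury log2 fold change with standard error (4 injured against 4 uninjured libraries) of 18 genes in the 3 genotypes; open points did not reach an adjusted p under 0.05, and Dro in homozygotes is set against 2 uninjured counts. Mtk and Drs rose in each genotype (3.33 ± 0.44 for Drs in homozygotes), while DptA in homozygotes was at 0.24 ± 1.35.

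The injury responses of the 3 genotypes shared more genes than chance would give. Wild type and heterozygotes shared 303 higher genes (15.1 expected) and 35 lower (0.900 expected), wild type and homozygotes 309 (21.9) and 23 (0.692), and heterozygotes and homozygotes 295 higher (21.2) and 43 lower. In each of the 3 genotypes 254 genes rose and 17 fell. Over the genes that rose in heterozygotes, the median log2 fold change was 0.85 in wild type and 0.83 in homozygotes. Over those that rose in wild type it was 0.78 in heterozygotes and 0.85 in homozygotes. Over those that fell in heterozygotes it was -0.37 in wild type and -0.26 in homozygotes. Across 13868 genes, which are not independent replicates, injury fold changes correlated at r = 0.66 between wild type and heterozygotes, 0.59 between wild type and homozygotes and 0.52 between heterozygotes and homozygotes. These pairs share no library.

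DptA, Def and PGRP-SB1, which did not pass in injured homozygotes, were not shown to respond differently from wild type as single genes. With edgeR 0 genes passed the test for a different injury response in heterozygotes against wild type (363 at unadjusted p under 0.05, where 693.4 are expected by chance) and 0 for homozygotes (647 unadjusted). DESeq2 called 0 (371 unadjusted) and 3 (730 unadjusted), and voom 0 (331) and 0 (486). In homozygotes minus wild type, the difference was -2.08 ± 0.70 for PGRP-SB1, -3.36 ± 1.28 for Def, -2.74 ± 1.57 for DptA, 1.82 ± 0.90 for Mtk and 2.70 ± 1.15 for AttA, each with an adjusted p of 0.934. In simulated data, a difference of responses was recovered for 39.5% of genes at 2-fold, 81.6% at 4-fold and 93.6% at 8-fold. Those counts were drawn around each gene's mean over all 24 libraries. The shares therefore do not apply to genes near 0 counts in homozygotes, such as DptA and Def, whose failure to pass is not informative. The simulated counts were also drawn gene by gene, without any structure between libraries that many genes share. For the other genes the shares may therefore be too high. As lists, the antimicrobial peptides moved down in this comparison (median -0.40, mean -0.22, camera adjusted p = 0.000390, or 0.617 with an estimated correlation), with a median of -0.18 without injured wild-type library 2, and the Bomanins did not pass (median 0.46, 0.192).

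The antimicrobial peptide score rose in every genotype after injury. It went from 1.63 ± 0.56 to 4.47 ± 0.43 in wild type, from 1.24 ± 0.57 to 3.98 ± 0.91 in heterozygotes and from -0.07 ± 0.14 to 1.67 ± 0.22 in homozygotes (mean ± SD of 4 libraries). Each of these 3 rises, and the lower score of homozygotes both uninjured (-1.70) and injured (-2.79), had a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 allows (adjusted p = 0.04, all 4 libraries of one group beyond the 4 of the other). Heterozygotes did not differ detectably from wild type uninjured (-0.39) or injured (-0.49), with an exact adjusted p of 0.371 for both. Summed over the 14 peptides, CPM rose from 83.1 ± 34.7 to 748 ± 236 in wild type, 61.8 ± 33.9 to 651 ± 408 in heterozygotes and 17.5 ± 4.62 to 185 ± 58.8 in homozygotes.

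Heterozygotes differed from wild type in few genes (4 libraries against 4). CG3397 had 0 counts in all 8 wild-type libraries and was at least 144-fold higher in uninjured and at least 185-fold higher in injured heterozygotes. mthl8 was at least 102-fold higher uninjured and 158-fold (43.8 to 1306) higher injured, and lncRNA:CR44333 at least 17.9-fold and at least 18.2-fold higher. Spn75F was higher by 4.94 ± 0.29 (adjusted p = 2.98e-10) uninjured and 4.98 ± 0.30 injured, and HSPBAP1 by 4.68 ± 0.41 and 4.41 ± 0.41. CG43680 was lower (-1.92 ± 0.23, adjusted p = 0.000367 uninjured and -1.56 ± 0.24 injured), as was Ugt35B1 (-1.07 ± 0.15 and -1.38 ± 0.15). CG13675 was lower uninjured (-1.37 ± 0.26, adjusted p = 0.0117), a call that ended without heterozygous uninjured library 1 (0.0603) or wild-type uninjured library 1 (0.0528), 2 (0.0669). Cyp6a2 was at 0.689 ± 0.636 CPM in injured wild type and 12.8 ± 7.46 CPM in injured heterozygotes (4.23 ± 0.87, adjusted p = 0.0296), a call that ended without heterozygous injured library 1 (0.0802), 2 (0.0602), 4 (0.0546) or wild-type injured library 1 (0.0584), 2 (0.129), 3 (0.0996), 4 (0.0940). sad was lower injured (-1.57 ± 0.30, adjusted p = 0.0152), a call that ended without heterozygous injured library 1 (0.0611), 3 (0.0889), 4 (0.0641) or wild-type injured library 1 (0.0690), 2 (0.0535). CG6927 was lower injured (-3.38 ± 0.74, adjusted p = 0.0489), against -0.52 ± 0.83, adjusted p = 0.899 uninjured, and its injured call ended without heterozygous injured library 1 (0.159), 2 (0.148), 3 (0.186), 4 (0.0873) or wild-type injured library 4 (0.501), where without wild-type injured library 4 the log2 fold change was -1.96. lncRNA:CR45378 was 26.5-fold (9.08 to 129) higher injured (adjusted p = 0.0140), a call that ended without wild-type injured library 2 (0.0823).

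Of the antimicrobial peptides, 0 passed in heterozygotes in either state, and DptA was at -1.99 ± 0.78 uninjured and 0.14 ± 0.61 injured. As a list they were lower uninjured (median -0.48, camera adjusted p = 0.0287, or 0.797 with an estimated correlation) and injured (-0.27, 0.00104, 0.674), and the Bomanins likewise (-0.28, 0.0162, 0.810 and -0.44, 0.000191, 0.674). Uninjured, the camera calls with 0 members passing were muscle (median -0.21, 5.01e-05), clock (0.23, 0.00329), Toll pathway (0.21, 0.00379), digestive enzymes (0.70, 0.00362) and testis (-0.11, 0.0215). Injured, they were muscle (0.24, 0.000310), digestive enzymes (0.50, 2.21e-05) and ribosomal proteins (0.19, 0.000348). None of these held with an estimated correlation. In total 69 genes passed uninjured (54 higher, 15 lower, 41 at least 2-fold) and 41 injured (30 higher, 11 lower, 35 at least 2-fold). Over all genes tested, the libraries did not overlap in 775 uninjured (5.59%) and 540 injured (3.89%), where chance gives 2.86%. Both states, which share no library, shared 25 higher genes (0.117 expected) and 6 lower (0.0119 expected). The uninjured count was 38, 33, 40 and 45 without wild-type library 1, 2, 3 and 4, and 35, 43, 150 and 45 without heterozygous library 1, 2, 3 and 4. The injured count was 26 without wild-type library 4 and 24 without heterozygous library 2, and the lower genes were 6 without wild-type library 4 and 7, 4 and 3 without heterozygous library 1, 2 and 4.

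Uninjured homozygotes had lower antimicrobial peptide genes than wild type (4 libraries against 4). Def (-4.03 ± 0.65, adjusted p = 0.000279), DptB (-5.88 ± 1.27, adjusted p = 0.00589), AttB (-3.23 ± 0.64) and CecA1 (-1.21 ± 0.24) were lower. AttD had 0 counts in homozygotes and was at least 12.1-fold lower, and Dro was 31.7-fold (8.79 to 262) lower. Drs did not pass (-1.33 ± 0.44, adjusted p = 0.106). Of the antimicrobial peptides, 0 of 14 measured members were higher, 11 lower and 3 did not pass (0 higher and 13 lower adjusted over the list alone), with a median of -3.82 and a camera adjusted p of 2.25e-17, and with members at 0 counts at their bound the median was -3.42. Of the Bomanins, 0 of 17 measured members were higher, 1 lower and 16 did not pass (0 higher and 1 lower adjusted over the list alone), with a median of -0.52 and a camera adjusted p of 0.00118 (adjusted p = 0.735 with an estimated correlation). Of the Imd pathway, 0 of 22 measured members were higher, 1 lower and 21 did not pass (0 higher and 3 lower adjusted over the list alone), with a median of -0.06 and a camera adjusted p of 0.00387 (adjusted p = 0.442 with an estimated correlation). With adjusted p in parentheses, DptA (-3.88 ± 0.96) lost its call without homozygous uninjured library 2 (0.0560), 3 (0.0663) or wild-type uninjured library 1 (0.111). Mtk (-2.81 ± 0.75) lost it without homozygous uninjured library 1 (0.108), 2 (0.0919), 4 (0.0637) or wild-type uninjured library 2 (0.276). AttA (-3.75 ± 0.94) lost it without homozygous uninjured library 3 (0.0719), 4 (0.0659) or wild-type uninjured library 1 (0.0754) and AttC (-4.03 ± 0.99) without homozygous uninjured library 2 (0.0573), 3 (0.0592) or wild-type uninjured library 2 (0.111). Dro lost it without homozygous uninjured library 1 (0.103), 2 (0.0944), 3 (0.0767), 4 (0.104) or wild-type uninjured library 1 (0.0756), 2 (0.174), 3 (0.0540), and AttD without homozygous uninjured library 1 (0.0614), 2 (0.0586), 3 (0.0773), 4 (0.0650) or wild-type uninjured library 1 (0.101).

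Uninjured homozygotes also differed from wild type in genes outside the immune lists. p24-2 was at 53.1 ± 9.32 CPM in wild type and 31.3 ± 7.96 CPM in heterozygotes and had 0 counts in homozygotes (at least 812-fold lower). CG43680 (at least 428-fold), CG32581 (at least 212-fold) and CG13675, 1374-fold (247 to 54260), were lower, as were Unc-115b (-7.84 ± 0.60) and Ugt35B1 (-7.30 ± 0.21, adjusted p = 3.79e-17). On the same strand of 3R, p24-2 (9687402 to 9692794) and Unc-115b (9687060 to 9692775) overlap, so they can share reads and may not be separate losses. CG3397 (at least 395-fold), mthl8 (at least 186-fold), lncRNA:CR44333 (at least 37.8-fold), lncRNA:CR44674 (at least 22.7-fold) and lncRNA:CR43846 (at least 23.1-fold) were higher, as were Spn75F (5.38 ± 0.30) and Cyp6a2 (4.14 ± 0.75). GstD3 (-1.36 ± 0.14), Lsp1gamma (-2.68 ± 0.55), Est-6 (-0.67 ± 0.15), Rh2 (-0.79 ± 0.17) and Thor (-0.77 ± 0.18) were lower and GstE1 (0.61 ± 0.10) higher. Of the eye list, 0 of 25 measured members were higher, 5 lower and 20 did not pass (0 higher and 11 lower adjusted over the list alone), with a median of -0.41 and a camera adjusted p of 3.58e-07 (adjusted p = 0.451 with an estimated correlation). Of digestive enzymes, 3 of 40 measured members were higher, 0 lower and 37 did not pass (11 higher and 0 lower adjusted over the list alone), with a median of 0.92 and a camera adjusted p of 5.01e-05 (adjusted p = 0.775 with an estimated correlation). Detoxification genes went both ways, 4 higher and 4 lower, with a median of 0.18, a mean of -0.02 and a camera direction upward that was not called (0.540). Camera adjusted p was 0.000677 for accessory gland, 0.00700 for glycolysis and 0.0162 for neuron genes, none passing with an estimated correlation. In total 549 genes passed, 276 higher and 273 lower, 328 of them at least 2-fold. Over all genes tested, the libraries did not overlap in 1440 (10.4%, chance 2.86%). Of the 38 named calls, 23 held with each library left out in turn.

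Injured homozygotes kept low levels of several peptides, while Drs, Mtk, AttA and Dro reached 30.2% to 51.7% of the wild-type level (4 libraries against 4). Def (-7.39 ± 0.72, adjusted p = 1.96e-07), DptA (-6.62 ± 0.92, adjusted p = 4.15e-05), DptB (-5.03 ± 0.73), AttC (-4.91 ± 0.63), CecC (-4.89 ± 0.66), CecB (-4.58 ± 0.62) and AttB (-3.78 ± 0.53) were lower, and AttD was 175-fold (31.3 to 6895) lower. Drs (-0.98 ± 0.39, adjusted p = 0.189), Mtk (-0.99 ± 0.46, 0.280), AttA (-1.05 ± 0.59, 0.382) and Dro (-1.54 ± 0.56, 0.144) did not pass. All homozygous libraries still lay below all wild-type ones for Drs (32.1 to 84.7 against 94.0 to 160 CPM) and Mtk (20.7 to 44.3 against 56.7 to 76.1). So they did for Dro (2.575 to 8.68 against 9.60 to 20.4), while those of AttA overlapped. Of all tested genes, 8.80% did not overlap. As a percent of the injured wild-type level, homozygotes had 51.7% of Drs, 44.5% of Mtk, 30.2% of Dro and 79.2% of IM1, but 1.05% of DptA, 3.06% of AttC and 0.527% of Def. PGRP-SB1 was lower (-3.21 ± 0.45, adjusted p = 5.14e-05), as were pirk (-1.64 ± 0.31), PGRP-SC1b (-5.05 ± 1.17) and PGRP-LB (-0.86 ± 0.18). Of the antimicrobial peptides, 0 of 14 measured members were higher, 10 lower and 4 did not pass (0 higher and 13 lower adjusted over the list alone), with a median of -4.18 and a camera adjusted p of 3.84e-21. Of the Imd pathway, 0 of 22 measured members were higher, 6 lower and 16 did not pass (0 higher and 6 lower adjusted over the list alone), with a median of -0.10 and a camera adjusted p of 0.00475 (adjusted p = 0.451 with an estimated correlation). Of the Bomanins, 0 of 17 measured members were higher, 2 lower and 15 did not pass (1 higher and 3 lower adjusted over the list alone), with a median of -0.27 and a camera adjusted p of 0.124. p24-2 (at least 789-fold), CG43680 (at least 288-fold) and CG32581 (at least 111-fold) were lower again, with Unc-115b (-8.29 ± 0.62), Ugt35B1 (-7.60 ± 0.22), sad (-4.39 ± 0.38), GstD3 (-2.02 ± 0.15), Hsp27 (-1.12 ± 0.21) and Acp54A1 (-1.09 ± 0.23). CG3397 (at least 471-fold) and mthl8, 251-fold (69.4 to 2071), were higher again, with Spn75F (5.65 ± 0.31), Cyp6a2 (5.35 ± 0.86), nSyb (1.07 ± 0.24) and sr (1.09 ± 0.21).

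In injured homozygotes camera adjusted p was 0.000113 for accessory gland, 0.000578 for activity-regulated, 0.00376 for neuron, 0.0231 for clock and 0.0287 for glycolysis genes, none passing with an estimated correlation. Detoxification genes had a median of 0.12 and a mean of -0.24, not called (0.238). In total 594 genes passed, 268 higher and 326 lower, 324 of them at least 2-fold. Over all genes tested, the libraries did not overlap in 1221 (8.80%, chance 2.86%). The higher genes were 165 and 172 without injured wild-type library 1 and 4. Of the genes that passed, 144 higher (5.33 expected) and 179 lower (6.42 expected) also passed in uninjured homozygotes. Of the 45 named calls, 37 held with each library left out in turn. Over all comparisons, 12 of 78 camera calls held with an estimated correlation: antimicrobial peptides after injury in wild type and heterozygotes and in both homozygote comparisons, Bomanins after injury in each genotype, the Imd pathway after injury in wild type and heterozygotes, and JAK-STAT after injury in each genotype.

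Genes that differed between homozygotes and wild type lay mostly on chromosome 3, which carries Rel. This comparison was chosen after the data were seen. Uninjured, 404 of 6120 tested chromosome 3 genes other than Rel passed (6.60%) against 141 of 7648 elsewhere (1.84%), an odds ratio of 3.76 (95% interval 3.09 to 4.61, two-sided Fisher's exact test, adjusted p = 2.06e-45 over 28 tests). Injured, the shares were 7.27% and 1.91% (odds ratio 4.03, exact adjusted p = 3.5e-53). For heterozygotes the odds ratios were 6.64 uninjured and 11.3 injured (exact adjusted p = 6.28e-11 and 5.01e-09). For injury they were 0.89 in wild type, 1.02 in heterozygotes and 0.97 in homozygotes (exact adjusted p = 0.293, 0.871 and 0.772). Neighbouring genes are not independent, so these p-values overstate the evidence. The differing genes were not only near Rel: within 5 Mb 7.58% of genes passed uninjured, and CG13675, CG43680, mthl8 and Spn75F lie on 3L.

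**Figure D3:**
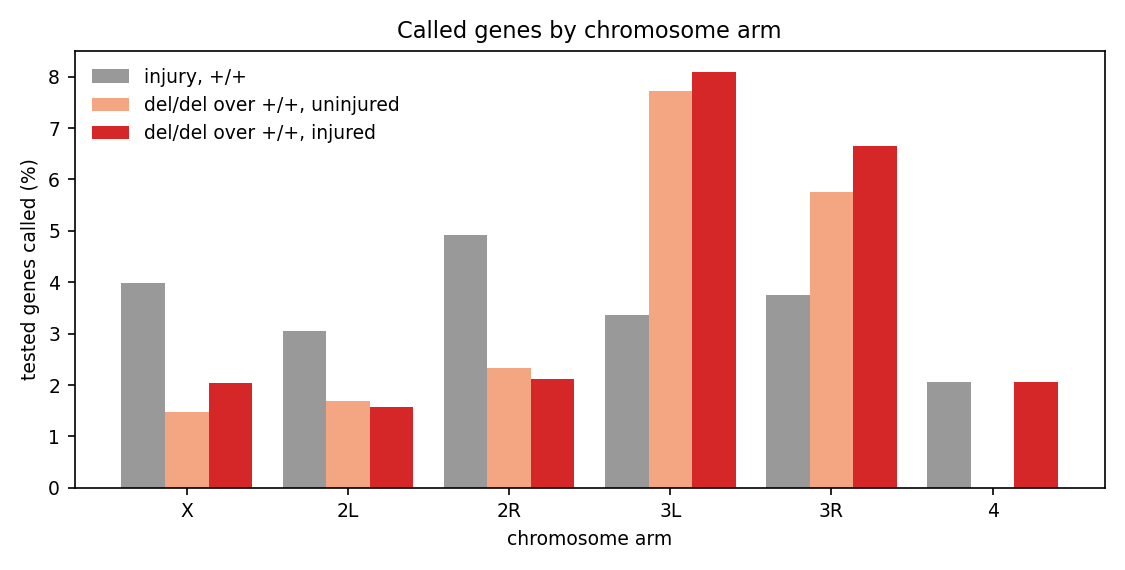
Percent of tested genes with an adjusted p under 0.05 on each chromosome arm, for injury in wild type and for homozygotes against wild type uninjured and injured; bars start at 0. On chromosome 3 as a whole 6.60% of genes passed between uninjured homozygotes and wild type, against 1.84% elsewhere.

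The authors' deposited tables called 900, 591, 567, 151, 867, 101 and 555 genes for injury in wild type, heterozygotes and homozygotes, heterozygotes and homozygotes uninjured, and heterozygotes and homozygotes injured. Of these, 487, 471, 484, 53, 517, 38 and 439 were called here too, with the sign of the authors' deposited tables. Across genes, which are not independent replicates, log2 fold changes of the authors' deposited tables and those here correlated at r from 0.986 to 0.998.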

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

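The tests on chromosome 3, on a mixed sample, on the Toll branch and on shared reads of Bomanins were chosen after their results were seen. So were the sums over single peptide families and the intervals of r for neuron genes. The tests on the sum over all antimicrobial peptides, on neuron and eye genes and on other splits of the libraries were written before their own results were seen. The neuron and eye pattern and the library tested for it were themselves picked from these data.

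For single libraries, 96 groups of 4 were searched for a value far from the other 3 (a gap to the nearest, over the group's range, above Dixon's 95% critical value), and 12 were found. Chance gives 1 in 20 groups, but not for the 4 found where the other 3 libraries had 0 counts (Rel, Dro in homozygotes and lncRNA:IBIN in 2 groups), since the gap then always equals the range. Uninjured wild-type library 1 held 6987499 counts, against 12366689 to 13244524 in the others. In uninjured homozygous library 2 the 10 most counted genes took 13.9% of the counts, against 8.46% to 8.59%. Rel was at 0.0997 CPM in uninjured homozygous library 1 (1 count) and 0 in the others. DptA was at 21.9 CPM in uninjured wild-type library 1 (2.70 to 5.003 in the others), Mtk at 8.55 CPM in uninjured wild-type library 2 (1.63 to 2.41), and Drs at 13.1 CPM in uninjured homozygous library 3 (3.72 to 4.39). Dro was at 2.71 CPM in uninjured heterozygous library 1 (0.358 to 0.533) and at 0.145 CPM in uninjured homozygous library 3 (0 in the others). IM1 was at 68.4 CPM in uninjured heterozygous library 1 (12.6 to 20.7). lncRNA:IBIN was at 0.242 CPM in uninjured wild-type library 2 and 0.0775 CPM in uninjured heterozygous library 1 (0 in the others of each group). Cyp6a2 was at 3.95 CPM in uninjured wild-type library 2 (0.621 to 1.16). Of the 12, all are in uninjured groups. No explanation of these values was tested.

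For 12 pairs of list and genotype, the injury response differed from that of wild type by camera on the difference of responses (median log2 difference, camera adjusted p, adjusted p with an estimated correlation). In heterozygotes these were muscle (0.44, 2.08e-13, 0.124), testis (0.16, 0.0235, 0.758) and the Toll pathway (-0.20, 0.000911, 0.695). In homozygotes they were activity-regulated genes (0.37, 4.99e-06, 0.113), antimicrobial peptides (-0.40, 0.000390, 0.617), clock (0.22, 0.0287, 0.427), detoxification (-0.24, 0.00575, 0.609), eye (0.46, 9.31e-08, 0.441), glia (0.19, 0.0287, 0.735), JNK, wound and death (0.22, 6.04e-05, 0.310), neuron (0.57, 2.65e-09, 0.579) and testis (-0.20, 0.0445, 0.797). Without injured wild-type library 2 the median of antimicrobial peptides was -0.18, and without uninjured wild-type library 3 that of eye genes was 0.31. None of the 12 held with an estimated correlation, and no member passed on its own with edgeR.

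Genes that differed between homozygotes and wild type lay mostly on chromosome 3. A loss of Relish as a regulator acting alike on all chromosomes is argued against by the odds ratio of 3.76 for chromosome 3, whose 95% interval (3.09 to 4.61) lies above that of injury in wild type (0.744 to 1.07). A chromosome 3 of other origin in the deletion stock is a candidate explanation: genes on chromosome 3 more than 5 Mb from Rel still had an odds ratio of 3.60. Large differences also lay on other chromosomes, such as CG32581 on X, with 0 counts in homozygotes, and Cyp6a2 on 2R. The cause of the differences on other chromosomes was not tested, so they cannot be assigned to Rel. Over 179 chromosome 3 genes called uninjured and at least 2-fold different in the injured libraries, heterozygotes lay there at a median of 0.487 of the way from wild type to homozygotes, which is consistent with each allele acting on its own copy, but 50 genes on other chromosomes lay at 0.40 (bootstrap interval 0.28 to 0.48), and with the states exchanged the medians were 0.451 and 0.438. More of the chromosome 3 genes than of the others lay between 0.25 and 0.75 (88.8% against 62.0%, and 88.1% against 57.4% with the states exchanged), so whether the midpoint is special to chromosome 3 stays open, as do effects of Rel on single genes there, because no second deletion line or rescue is among the groups.

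Antimicrobial peptide and Bomanin genes rose after injury in homozygotes, which had 0 or 1 Rel counts per library. RNA of another genotype in these samples is argued against by Rel itself: 3 counts over the 4 injured homozygous libraries would be 0.0502% of the injured wild-type level, while Drs was at 51.7%. Reads moved between near-identical copies within a list or family leave its sum unchanged. The sums over the 14 peptides, the diptericins and the 17 Bomanins and other Toll peptides (423 ± 74.6 to 2441 ± 653 CPM) each rose without overlap (two-sided exact permutation p = 0.0286). This argues against such sharing as the source of each summed rise, but does not show which copy rose. Drs and Mtk gave 63.7 ± 22.4 and 32.6 ± 12.3 of the 185 ± 58.8 CPM summed over the 14 peptides in injured homozygotes. An attacin sum also rose, but it included att-ORFB, which is not among the 14, so it is not used. The cecropins, with no called member, were at 8.07 ± 0.864 and 10.02 ± 2.41 CPM (exact p = 0.143). Induction through the Toll branch may account for the rise: the Bomanin response of homozygotes minus wild type had a median of 0.46, and stayed above 0 (0.18 to 0.63) with each library left out. The larger response starts from a lower level: the mean Bomanin sum was 423 ± 74.6 CPM in uninjured homozygotes and 614 ± 223 CPM in uninjured wild type. Injured, it was 2441 ± 653 and 2788 ± 664 CPM. The explanation through the Toll branch was formed on these data and remains a hypothesis.

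Neuron and eye genes differed in the injury response between homozygotes and wild type by camera with a preset correlation, which did not hold with an estimated correlation (adjusted p = 0.579 and 0.441), and no member passed with edgeR. An unequal share of head RNA and one of abdominal RNA both stay open, because intervals of r within groups (24 libraries, Fisher's z on 18 residual degrees of freedom) are too wide to decide. The neuron score correlated with the eye score at r = 0.518 (95% interval 0.0837 to 0.787, permutation p = 0.0299, adjusted p = 0.0897 over 3 relations, rho = 0.699, permutation p = 0.00137, r without the 2 farthest libraries 0.651), and with the testis and accessory gland score at r = -0.20 (-0.60 to 0.28, permutation p = 0.254, adjusted p = 0.381, rho = -0.17, permutation p = 0.425, r without the 2 farthest libraries -0.18), while testis genes had a median of -0.20 in the same difference of responses and accessory gland genes were lower in injured homozygotes than in wild type by camera (0.000113, or 0.753 with an estimated correlation). Injured homozygous library 1 stood apart on the third principal component (66.5 against 26.2, 3.37 and -4.69 in the others of its group), and without it the median difference fell from 0.549 to 0.304 over both lists, a share of 0.554, and from 0.57 to 0.22 over the neuron list alone, so that library cannot be told apart from the group as the source. A biological difference between genotypes stays open and was not tested separately.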

How the results depend on the processing

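No named call, called list median, peptide score or size of response changed sign under the alternatives it was refitted with. The other called genes were counted but not compared for sign. The settings with thinned counts, with the log2 library total as a covariate and with only libraries of more than 9000000 counts were chosen after seeing the data. Counts below are in the order injury in wild type, heterozygotes and homozygotes, then heterozygotes and homozygotes uninjured, then heterozygotes and homozygotes injured. At an adjusted p under 0.01 they were 272, 293, 379, 30, 332, 21 and 316 (19, 52, 35, 5, 169, 3 and 192 lower). A change of at least 2-fold left 246, 271, 259, 41, 328, 35 and 324 (25, 65, 31, 5, 160, 6 and 193 lower). With only the groups compared, 647, 278, 353, 33, 663, 21 and 284 passed, more than with all groups for injury in wild type and homozygotes uninjured, and fewer for the others, with 115, 44, 43, 9, 334, 6 and 174 lower. With only libraries of more than 9000000 counts, 253, 394, 265, 39, 539, 18 and 251 passed (13, 85, 31, 11, 284, 5 and 159 lower), with 2 to 4 libraries per group. DESeq2 called 651, 958, 1160, 141, 683, 70 and 738 (104, 360, 336, 39, 345, 21 and 404 lower), and 3 for the difference of responses in homozygotes. Lower genes also moved by over 1.5 times with the covariate (106 for injury in homozygotes), and for heterozygotes against wild type with thinned counts (9 uninjured, 7 injured), voom (20 injured) and a replicate block (6 injured). The cause was not tested for DESeq2 or for only the groups compared.

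Leaving out 1 library gave 302 to 450, 380 to 1495, 484 to 1582, 33 to 150, 407 to 575, 24 to 39 and 433 to 739 genes, and 0 for both differences of responses. Medians of the injury response moved in 9 of 144 omissions: that of homozygotes over genes that fell in heterozygotes ranged from -0.30 to -0.20, and r ranged from 0.477 to 0.619 (wild type and homozygotes) and 0.410 to 0.560 (heterozygotes and homozygotes). Of the named calls, 2095 were kept and 361 lost over these omissions, 270 were kept and 37 lost with voom, 305 and 2 with DESeq2, 239 and 58 with only the groups compared, 274 and 26 with thinned counts, 287 and 20 with the covariate, and 202 and 105 with the deeper libraries. With a replicate block 283 were kept and 24 lost, with no filter on low counts 297 and 10, and with median-ratio factors 305 and 2. The peptide score kept its side of the threshold under every alternative that could reach it. Of 78 list calls, 12 held with an estimated correlation and 31 with fry.

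The numbers 1 to 4 were not used to pair the libraries, because the labels do not say what they mark. Residuals of same-numbered libraries correlated at -0.435 to 0.291 across genes, which are not independent replicates. These values show no consistent pairing but cannot exclude a shared day or culture. As a replicate block the numbers gave 484, 555, 742, 50, 521, 30 and 527 genes, 0 and 0 for the differences of responses, and 80 list calls. Sign flips of 4 paired differences cannot go below an exact p of 0.125. Counts thinned to the smallest library gave 424, 575, 774, 47, 473, 29 and 531 genes, each within 1.5 times the count at full depth. With these libraries, simulated 1.5-fold changes were recovered for 28.0% of genes for injury in wild type and 6.67% for a difference of responses in homozygotes.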

Other observations

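The families below were chosen by the start of the gene symbol after the data were seen. The tests of other splits were written before.

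Of 20 families (180 tests), the smallest camera adjusted p was that of 40 complex I genes for the injury response of heterozygotes minus wild type (median 0.30, 8.47e-08), where ATP synthase genes had a median of 0.39 (1.49e-05) and Cyp genes one of -0.32 (2.67e-05). Complex I genes had a median of 0.38 after injury in heterozygotes (2.48e-05) and of 0.31 in injured heterozygotes against wild type (4.1e-06), and 0 passed in these comparisons. In uninjured homozygotes against wild type the medians were 0.31 for complex I (5.55e-05, 1 gene lower) and 0.46 for ATP synthase genes (0.000722). Proteasome genes had a median of -0.20 for the response of homozygotes minus wild type (4.06e-06). After injury in heterozygotes, of 80 Cyp genes 2 rose and 12 fell (median -0.39, camera adjusted p = 5.48e-07), and of 29 Ugt genes 0 rose and 6 fell (median -0.57, camera adjusted p = 8.92e-06). Uninjured, heterozygotes against wild type had medians of 0.24 for Cyp (8.92e-06) and 0.42 for Ugt genes (0.000138). Of 35 Gst genes 7 rose and 1 fell after injury in wild type (median 0.19, camera adjusted p = 0.0012), and the response of homozygotes minus wild type had a median of -0.25 (6.42e-05). None of these held with an estimated correlation (adjusted p = 0.804 for Ugt after injury in heterozygotes and Gst in the difference of responses, and 0.921 for the others). Cyp, Ugt and Gst genes include members of similar sequence, so single values are uncertain.

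The 3 genes that DESeq2 called for a different injury response in homozygotes are named after their values were seen. GstE10 (log2 difference -1.32, adjusted p = 0.0279) went from 7.85 to 18.9 CPM in wild type and from 11.2 to 10.7 CPM in homozygotes. inaF-B (1.42, adjusted p = 0.0279) went from 104.6 to 48.5 and from 73.0 to 90.2 CPM. Smvt (-1.14, adjusted p = 0.0325) went from 81.4 to 113.5 and from 165.5 to 103.3 CPM. With edgeR GstE10 and Smvt had adjusted p of 0.432 and 0.472, and 0 genes passed (647 at unadjusted p under 0.05).

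Other splits of the same libraries were refitted with only the groups concerned. The real split called the most genes for injury in wild type (647 genes, highest other split 241), heterozygotes (278 and 81) and homozygotes (353 and 1). It also did for homozygotes against wild type uninjured (663 and 16) and injured (284 and 40). In each of these only the real split, 1 of 35, was as large. That is the smallest share 35 splits can give, so this count goes against chance but cannot exclude it. For heterozygotes against wild type, 2 of 35 splits were as large uninjured (33 genes) and injured (21 genes), so there the count does not go against chance. The 2 states share no library, however, and shared 25 higher genes (0.117 expected) and 6 lower (0.0119 expected), so chance does not account for the shared genes. CG3397 had 0 counts in all 8 wild-type and 74 to 230 in all 8 heterozygous libraries. In these comparisons the highest other split gave 1080 genes (wild-type libraries 1 and 4 with heterozygous libraries 2 and 3) and 118 genes (wild-type libraries 1 and 3 with heterozygous libraries 1 and 4), which points to a structure of these samples that the labels do not give. Uninjured, the libraries named had digestive enzyme scores (mean log2 CPM over the list) of 3.96 to 5.06, against 2.19 to 3.29 in the others. Injured, the 2 sides overlapped (4.37 to 5.32 against 3.42 to 4.53). This list was picked after its values were seen, and no cause was tested. For the differences of responses 0 genes passed, so 100 of 100 drawn splits were as large, with a highest other of 213 in heterozygotes and 1 in homozygotes.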
